A study of Rattus norvegicus with 4 samples.

How the data were processed

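Total RNA of the spinal dorsal horn was measured on 4 Agilent 2-colour rat arrays, 2 of oxaliplatin-treated and 2 of vehicle-treated rats. Per the labels, channel 1 (Cy3) held RNA of untreated rats and channel 2 (Cy5) RNA of the treated rats on every array, with no dye swap, while the extract protocol describes Cy3 labelling only. Groups and replicate numbers were taken from the sample titles, and 0 columns were left unmapped. Per the file headers, the scanner files hold the intensity of each spot and of its local background, as median pixel signals per channel. Per the file headers they also hold Agilent's processed intensity, after background subtraction and dye normalisation, and its log10 ratio of Cy5 over Cy3. The headers name Agilent Feature Extraction 10.7.1.1, and the submitters' processing notes name 8.5.1.1. The value table of the authors holds log10 ratios of Cy5 over Cy3, which matched the scanner files' log ratio by spot number with a largest gap of 0.0050. Its medians were -0.00277, 0, -0.00492 and -0.00316 for oxaliplatin replicates 1 and 2 and vehicle replicates 1 and 2. The flags of the scanner software, per the file headers, mark spots that are well above background, saturated or outliers, and hold other values than signals. Flags of saturation were set for 1 Cy3 spot on oxaliplatin replicate 1 and for 0 spots elsewhere.

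The plan, fixed before the data were examined, named mean signals, but the files hold median signals only, so these were used. Signals were corrected for background with normexp (offset 50) in limma 3.58.1 under R 4.3.3, and the log2 Cy5/Cy3 ratios were normalised by loess within arrays, with control spots at weight 0. Control spots (4259 per array) were left out, as were spots marked as outliers (1730 on any array) on the arrays concerned, and spots of a probe were averaged. Of 30367 probes, 30358 had a value on every array, and 26002 were kept because Cy5 was well above background on at least 2 arrays. Duplicate spots of a probe differed with an SD of 0.05 to 0.06 (log2). Probes were named through the accession in the files, matched without version to the reference table of rat genes, and 18758 probes had a symbol. The others kept the name in the files. Positions were not used here. Each gene was represented by its probe with the highest mean signal, which left 22821 genes, 13908 of them with a symbol. For 2884 genes with several kept probes, the probes disagreed in the sign of the difference for 1291. Single-channel signals were normalised by Aquantile and quantile within each channel, and the bound for a gene not well above background in a group used the higher of that array's lowest signal well above background and the probe's own signal, with the lower bound of the 2 normalisations given.

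Oxaliplatin was compared with vehicle by lmFit and eBayes in limma (two-sided, residual df 2, prior df 4.74), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Each group's ratio was also tested against 0. The 37 gene lists (819 symbols, 818 of them in the reference table) were fixed before any values were seen. They were tested by camera with a preset correlation of 0.01 where at least 5 members were measured, with an estimated correlation, and by fry, which tests whether a list's genes move on balance in 1 direction and compares it with no other genes. Every call of a list by camera was lost with the estimated correlation, where the smallest adjusted p was 0.923. With an estimated correlation camera rests on the residual df of 2, so few lists could pass. The DNA methylation and histone enzyme list had an estimated correlation of -0.0017, below the preset, yet its camera p rose from 0.041 to 0.16. A call lost there is therefore not shown to come from correlation between genes. The forebrain list of 18 genes was added after the data were seen, and a list of 25 Hox genes after the data were seen but before its own values were looked at. Named genes were the 12 in each direction with adjusted p under 0.05, or, where fewer passed, the non-overlapping genes with a symbol and the smallest unadjusted p. To these were added up to 4 members of each list described with the smallest unadjusted p, and 8 genes named whatever their values. Some genes that the rule picks are not reported here, and no other genes took their place.

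The fit was tested on simulated data, with the mean ratio of each gene and spreads drawn from the prior fitted to these arrays. Of 100 genes changed 2-fold it recovered 72%, and of 100 changed 4-fold 100%, while 5 unchanged genes were called. A list of 17 genes shifted by 0.4 gave an adjusted p of 7.20e-12 by camera, and 0 other lists were called. Genes were drawn independently there, while estimated correlations in the real lists reached 0.71 (interferon genes). The simulation therefore does not show how often lists are called falsely on these arrays. Alternatives fixed in advance were the scanner software's log ratio, median centring, no background correction, no filter, a filter on all 4 arrays, the mean over a gene's probes, each probe on its own, the authors' value table, a trended and robust variance, the replicate block, Cy5 alone, and leaving out each array in turn. Where an array was left out, the lone array of its group was assumed to vary like the other group. Cy3 alone, scaled ratios, a filter on Cy3 as well, Cy5 alone for the lists and the crossed pairing were chosen after seeing the data.

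Same-numbered arrays share no stated pairing. The deviations of same-numbered arrays from their group means correlated by -0.22 across genes, so the unpaired fit was kept as the main one. Both oxaliplatin arrays came from 1 slide and 1 scan, and both vehicle arrays from another slide and 2 other scans. No slide or scan held both groups, so neither could enter as a block, and slide and group cannot be told apart. A random block by scan could not be fitted, since duplicateCorrelation in limma gave an estimate for 0 genes.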

Results

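Gene expression was measured in the dorsal horn of the spinal cord, the region that receives sensory input, in male rats aged 6 weeks on day 10. The rats had received oxaliplatin, a platinum chemotherapy drug whose side effects include a painful neuropathy, or its vehicle. There were 4 Agilent 2-colour arrays, 2 of the oxaliplatin group and 2 of the vehicle group, which the labels call biological replicates. Whether an array held RNA of a single rat or of several is not given in the sources used here. The p-values rest on the spread of the Cy5/Cy3 ratios between the arrays of a group, to which both channels add. Each group had a slide of its own, so that spread holds no difference between slides. Per the labels, the Cy5 channel of each array held RNA of the treated rats and the Cy3 channel RNA of untreated rats. Each array carried 62976 spots, of which 4259 were controls. In Cy5, 82.6% to 85.4% of probes were well above background. In Cy3 the range was 76.8% on oxaliplatin replicate 2 to 88.1% on vehicle replicate 1. The median Cy3 signal was 283.5 on oxaliplatin replicate 2 and 494 to 564 on the other arrays. The number of arrays limits the precision.

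The direction of change in the rats is not settled by these arrays, for reasons given as values. The Cy5 channel carried transcripts of tissues other than the cord on all 4 arrays. Schwann cell and dorsal root ganglion genes, a list fixed in advance, had a median log2 Cy5/Cy3 ratio of 2.83 on the vehicle and 2.80 on the oxaliplatin arrays. Of them, Scn10a, a sodium channel of sensory neurons whose cell bodies lie in the ganglia outside the cord, had ratios of 4.97 to 5.76. Both channels differed between the groups, with an SD of the group difference over the 22821 genes of 0.39 in Cy5 and 0.46 in Cy3, correlated by 0.85. The difference in the ratio, which is made of both, correlated by -0.67 with that in Cy3 and by -0.19 with that in Cy5. The protocol text for the extracts names Cy3 labelling only. Every difference is therefore given as the Cy5/Cy3 ratio on the oxaliplatin arrays minus that on the vehicle arrays. If Cy5 held the treated rats' RNA, as the labels state, a higher ratio means a higher level only relative to the untreated RNA on the same array. The Cy5 signal itself need not be higher then, given its correlation of -0.19 above, and a fall in Cy3 alone raises the ratio. If Cy3 held the treated rats' RNA, a higher ratio means a lower level after oxaliplatin relative to Cy5.

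The comparison of oxaliplatin with vehicle asks which transcripts of the dorsal horn differ after the drug. Of 7 genes of MHC class II, which presents antigen to T cells, 5 had a higher Cy5/Cy3 ratio on the oxaliplatin arrays, and the list was called higher, a call lost with an estimated correlation (adjusted p = 0.923 with an estimated correlation). The ratio of RT1-Bb was higher by 1.55 ± 0.19 (SE, n = 2 arrays per group, log2). That of Cd74, the chaperone of the class II molecules, was higher by 1.53 ± 0.28. Genes of myelin and of astrocytes, the glia that support neurons, also had higher ratios as groups, but these calls were lost with an estimated correlation (adjusted p = 0.923 with an estimated correlation). Ribosomal protein genes had slightly lower ratios as a group, a call lost in the same way (adjusted p = 0.923 with an estimated correlation), with median centring and without either of 2 arrays. The test with an estimated correlation rested on a residual df of 2 and had little power, so these losses leave the lists undecided. No single gene passed the test.

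Of the 7 measured MHC class II genes, 5 had higher ratios and 2 lower, with a median difference of 1.19 (camera, adjusted p = 4.95e-04; median 0.68 with no filter on dim probes). That call was lost with an estimated correlation (adjusted p = 0.923 with an estimated correlation) and by fry (adjusted p = 0.453). The list's median ratio was 0.11 and 1.06 on oxaliplatin replicates 1 and 2 and -0.25 and -0.24 on the vehicle arrays. In that median the oxaliplatin arrays lay further apart from each other than the groups did (0.95 against 0.82). It fell on Cd74 on both oxaliplatin arrays and on RT1-DMa on both vehicle arrays, so it compares different genes. Both oxaliplatin ratios lay above both vehicle ratios for 5 of the 7 genes and below for 0. Over all genes the groups were apart, in either direction, for 49.2%. For RT1-Bb the ratios were 0.90 and 1.47 against -0.44 and -0.29, and for Cd74 0.11 and 1.06 against -1.01 and -0.88. RT1-Bb was at 1.01 with the mean over its probes. RT1-Da differed by 1.26 ± 0.17 and RT1-Db1 by 1.19 ± 0.18. RT1-DMa, RT1-DMb and the class II transactivator Ciita differed by 0.17, -0.010 and -0.036, and Ciita was well above background in Cy5 on 1 of the 2 oxaliplatin arrays. None of the 7 passed over all genes tested (0 genes), and 4 passed when adjusted over the list alone. The list's median differed by -1.10 in Cy3 and by -0.15 in Cy5. In Cy5 alone, therefore, the direction was the opposite and the list was not called (adjusted p = 0.719).

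The oligodendrocyte and myelin list, genes of the cells that wrap axons, had a median difference of 0.38 (camera, adjusted p = 8.56e-05; adjusted p = 0.923 with an estimated correlation; fry adjusted p = 0.453). Of its 18 members, 15 had higher ratios and 3 lower. Mag, an adhesion protein of the myelin sheath, differed by 0.72 ± 0.17. Cldn11, the tight junction protein of myelin, differed by 0.79 ± 0.19, and Sox10, a transcription factor of oligodendrocytes, by 0.60 ± 0.14. No member passed over all genes (0 genes), and 7 passed when adjusted over the list alone. The list's median ratio on oxaliplatin replicate 1, -1.27, lay below that on vehicle replicate 1, -1.23, so the arrays of the groups overlap in that median. Member by member, both oxaliplatin ratios lay above both vehicle ratios for 11 of the 18 and below for 0. Over all genes the groups were apart, in either direction, for 49.2%. Without oxaliplatin replicate 2 the median difference was 0.24. The list's median differed by -0.41 in Cy3. In Cy5 it differed by -0.17, opposite to the ratio, and the list was not called in that channel alone (adjusted p = 0.491).

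The astrocyte markers had a median difference of 0.42 (camera, adjusted p = 8.56e-05; adjusted p = 0.923 with an estimated correlation; fry adjusted p = 0.453). Of 16 markers, 15 had higher ratios and 1 lower. Aldh1l1, a folate enzyme of astrocytes, differed by 0.64 ± 0.18, the calcium-binding protein S100b by 0.61 ± 0.16, angiotensinogen (Agt) by 0.54 ± 0.13 and glutamine synthetase (Glul) by 0.45 ± 0.12. Aldh1l1 was at 0.41 without vehicle replicate 2 and S100b at 0.40 without oxaliplatin replicate 2. No marker passed over all genes (0 genes), and 7 passed when adjusted over the list alone. The list was not called in Cy3 alone, where its median differed by -0.19 (adjusted p = 0.454), nor in Cy5 alone, where it differed by 0.040 (adjusted p = 0.913). The myelin and astrocyte lists had median ratios below 0 on all 4 arrays, except that with median centring in place of loess the astrocyte median was 0.40 on oxaliplatin replicate 2.

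The 38 ribosomal protein genes had a median difference of -0.10 (camera, adjusted p = 0.0366; adjusted p = 0.923 with an estimated correlation; fry adjusted p = 0.599), with 27 lower and 11 higher. Rpl14, Rps3 and Rpl22 differed by -0.37, -0.34 and -0.33, and no member (0 genes) passed when adjusted over the list alone. With the mean over probes Rpl14 was at -0.080 and Rps3 at -0.21. Leaving out an array gave Rpl14 -0.56 to -0.18, and without vehicle replicate 2 Rps3 was at -0.18. This call was also lost without oxaliplatin replicate 1 (adjusted p = 0.284) and without vehicle replicate 2 (adjusted p = 0.217), in Cy5 alone (median -0.099, adjusted p = 0.719) and in Cy3 alone with its sign turned (median -0.079, adjusted p = 0.436). With median centring in place of loess the direction of the test turned and the median was -0.0040 (adjusted p = 0.981).

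**Figure D1:**
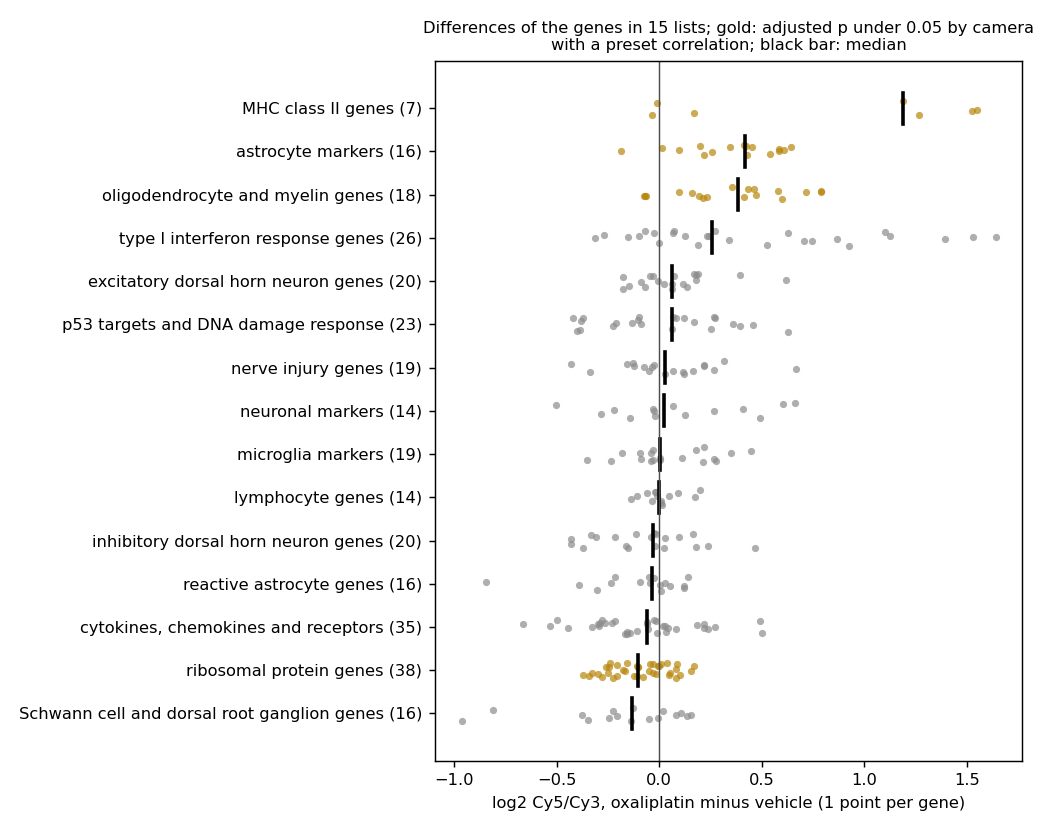
Difference of the log2 Cy5/Cy3 ratio, oxaliplatin minus vehicle, for each measured gene (points) of 15 lists, with the list's median (black bar) and, in gold, the lists with an adjusted p under 0.05 by camera with a preset correlation, all of which lost that call with an estimated correlation. The MHC class II median lies at 1.19, the astrocyte median at 0.42 and the myelin median at 0.38, and the myelin and MHC class II medians have the opposite sign in Cy5 alone.

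The other 11 lists described were not called. The type I interferon response genes, which act against viruses, had a median difference of 0.26 (adjusted p = 0.112) that depended on single arrays. It was 0.83 without oxaliplatin replicate 1 (adjusted p = 1.56e-10), 0.60 without vehicle replicate 1 (adjusted p = 5.67e-05) and -0.29 without oxaliplatin replicate 2 (adjusted p = 0.0112). The list was also called, with higher ratios, with median centring (0.35, adjusted p = 0.0175), the mean over probes (0.31, adjusted p = 0.0439), the replicate block (0.26, adjusted p = 0.0242) and scaled ratios (0.33, adjusted p = 0.0449). Without vehicle replicate 2 its median was 0.090 (adjusted p = 0.685). Its median had the opposite sign in Cy5 alone, -0.033. Ifit3, which restrains viral replication, differed by 1.64 ± 0.54, and by 0.74 to 2.54 when leaving out an array.

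Microglia markers, from the resident macrophages of the cord, had a median difference of 0.0044 (adjusted p = 0.832), with P2rx4, an ATP-gated channel, at 0.35 (0.20 to 0.50 when leaving out an array) and the lysosomal protein Cd68 at -0.35 (-0.62 to -0.083). The median was 0.35 without oxaliplatin replicate 1 (adjusted p = 0.0053) and -0.17 without oxaliplatin replicate 2 (adjusted p = 0.0013). It was 0.14 without vehicle replicate 1 and -0.077 without vehicle replicate 2, and -0.12 in Cy5 alone. Reactive astrocyte genes had a median of -0.033 (adjusted p = 0.333; -0.19 to -0.0088 when leaving out an array), with Emp1 at -0.39 (-0.23 without oxaliplatin replicate 1) and the hyaluronan receptor Cd44 at -0.30 (-0.12 with median centring), and a median of 0.013 in Cy5 alone and also with scaled ratios. Cytokines, chemokines and their receptors had a median of -0.061 (adjusted p = 0.218), with the receptors Tnfrsf1a at -0.50 (-0.32 with median centring) and Cxcr4 at 0.50 (0.28 without vehicle replicate 1). That list was called lower without oxaliplatin replicate 2 (-0.044, adjusted p = 0.0066), without vehicle replicate 1 (-0.15, adjusted p = 0.0367) and with median centring (-0.32, adjusted p = 0.0135), and had a median of 0.055 in Cy5 alone. Leaving out an array gave it a median of -0.15 to -0.032. Lymphocyte genes had a median of -0.0022 and a mean of 0.012 (adjusted p = 0.911), and were called lower with median centring (-0.33, adjusted p = 0.0235). Their test pointed to higher ratios, and to lower ones without oxaliplatin replicate 2 (median 0.070) and without vehicle replicate 2 (median 0.0024).

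Neuronal markers had a median difference of 0.025 (adjusted p = 0.445), with 7 higher and 7 lower. Among them were the ubiquitin hydrolase Uchl1 at 0.66 and the RNA-binding proteins Elavl3 at 0.60 and Elavl4 at -0.50. The markers' median was -0.043 without oxaliplatin replicate 1, 0.16 without oxaliplatin replicate 2 and -0.069 without vehicle replicate 1. They were called higher without vehicle replicate 2 (0.18, adjusted p = 0.0443), and had a median of -0.12 in Cy5 alone. Genes of excitatory dorsal horn neurons had a median of 0.064 (adjusted p = 0.445; medians of -0.050 in Cy5 alone, 0.034 without oxaliplatin replicate 2 and 0.0086 with the scanner software's log ratio), with the matrix protein Reln at 0.39. Genes of inhibitory neurons had a median of -0.031 (adjusted p = 0.333; medians of 0.022 in Cy5 alone, -0.12 without vehicle replicate 1, -0.079 without vehicle replicate 2 and -0.15 with the scanner software's log ratio), with the glycine transporter Slc6a5 at -0.43 (-0.24 without vehicle replicate 2). Targets of p53 and DNA damage genes had a median of 0.061 and a mean of 0.014, while the test pointed to lower ratios (adjusted p = 0.845). Among them the kinase Plk3 was at 0.46 and the ribonucleotide reductase subunit Rrm2b at -0.42 (-1.07 with the scanner software's log ratio). The median was -0.065 without vehicle replicate 2. The direction of that test turned without oxaliplatin replicate 2 (median 0.044), without vehicle replicate 1 (0.041), with median centring (0.17), with the mean over probes (0.061) and in Cy5 alone (0.043).

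Nerve injury genes had a median difference of 0.028 (adjusted p = 0.832; medians of -0.029 without oxaliplatin replicate 1, 0.095 without oxaliplatin replicate 2, -0.0016 without vehicle replicate 1 and -0.0088 in Cy5 alone), with the peptide Crh at -0.43 (-0.22 with the mean over its probes). Schwann cell and dorsal root ganglion genes had a median of -0.13 (adjusted p = 0.333). Without vehicle replicate 1 they were called lower (-0.31, adjusted p = 0.0014), and without vehicle replicate 2 the direction turned (0.075). Without oxaliplatin replicate 2 the median was 0.062. The other 22 lists had medians of -0.19 to 0.29, and their smallest adjusted p was 0.112. Of these, 10 were called under some alternative, 8 of them when an array was left out. Without vehicle replicate 2, glucocorticoid response genes were called lower (-0.57, adjusted p = 6.32e-11) and cell cycle genes lower (-0.21, adjusted p = 4.82e-05), and without oxaliplatin replicate 2 erythrocyte genes were called higher (0.91, adjusted p = 1.60e-05).

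Among single genes, the named genes with higher ratios and the smallest p included Retsat, Atf6b, RT1-Bb, Shox2, RT1-Da, Nbl1, Pygm, Myo18a, Ip6k2, Fjx1 and Pja2. Retsat, which saturates retinol, differed by 1.03 ± 0.12 (SE, n = 2 arrays per group). Atf6b, a sensor of unfolded proteins, differed by 1.01 ± 0.13 and the muscle glycogen phosphorylase Pygm by 0.93 ± 0.13. Shox2, a homeobox factor, differed by 0.93 ± 0.12 in the ratio and was higher on the oxaliplatin arrays in both channels, by 2.38 in Cy5 and 1.14 in Cy3. It was well above background in Cy3 on 1 of the 2 vehicle arrays, and 1 of its 2 probes had the opposite sign. It was at 0.34 with the scanner software's log ratio and at 0.37 with the mean over its probes, with which Pja2 was at 0.44. The 12 named genes with lower ratios and the smallest p were Oxnad1, Chdh, Bphl, Crygb, Mgmt, Prim1, Hira, Hes1, Angptl4, Serpinb1a, St14 and Clec10a. Chdh, which oxidises choline, differed by -1.18 ± 0.12, the DNA repair gene Mgmt by -0.88 ± 0.12 and the protease inhibitor Serpinb1a by -1.74 ± 0.33. Hes1, a repressor downstream of Notch, differed by -1.38 ± 0.24, with higher signals on the oxaliplatin arrays in both channels, by 0.90 in Cy5 and 2.19 in Cy3. Crygb, a lens crystallin, differed by -0.88 ± 0.11, by -0.40 with the scanner software's log ratio and by -1.33 with median centring, with lower signals in both channels, and was well above background in Cy3 on 1 of the 2 oxaliplatin arrays.

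Oxnad1 was not well above background on either vehicle array in either channel, so its difference has only a bound. Its signal on the oxaliplatin arrays was at least 1.29-fold higher in Cy5 and at least 3.28-fold higher in Cy3, the lower of 2 normalisations, from dyes that were not swapped. Its fitted ratio gave an adjusted p of 0.149, and of 0.0491 with the ratios scaled to a common spread. Of the genes named in advance whatever their values, Atf3, which injured neurons induce, was at 0.67 ± 0.20, the astrocyte filament gene Gfap at 0.43 ± 0.25 and the chemokine gene Cxcl12 at 0.27 ± 0.13. The p53 target Cdkn1a was at 0.12 ± 0.11, Tnf at 0.22 ± 0.30, Il1b at -0.26 ± 0.25, Ccl2 at -0.33 ± 0.20 and the microglial gene Aif1 at -0.028 ± 0.28. When leaving out an array Atf3 was at 0.43 to 0.91, Gfap at 0.099 to 0.75, Cxcl12 at 0.17 to 0.37 and Ccl2 at -0.63 to -0.028. Cdkn1a was at 0.27 with median centring. Directions turned for Aif1 without oxaliplatin replicate 1 (0.44), without vehicle replicate 1 (0.035), with median centring (0.069), with the mean over its probes (0.050) and with scaled ratios (0.030). They also turned for Tnf without vehicle replicate 1 (-0.29), for Il1b without vehicle replicate 2 (0.15) and for Cxcl12 with the mean over its probes (-0.031).

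Of the 22821 genes tested with limma, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.0948. At an unadjusted p under 0.05 there were 3342 genes, 2007 with higher and 1335 with lower ratios, where chance alone gives 1141. This count was 929 without vehicle replicate 2 and 6161 without oxaliplatin replicate 1, and with median centring 1769 genes were higher and 2003 lower. Of 81 named genes, 34 moved by over 1.5 times or turned direction when an array was left out. The count past the threshold was 937 without oxaliplatin replicate 1, 15 without oxaliplatin replicate 2, 33 without vehicle replicate 1 and 2 without vehicle replicate 2. Those 2 genes were Eml1, a microtubule-associated protein, at 2.31 and the kinase Sgk1 at -2.33. The count was 1 with a trended and robust variance, 3 with the replicate block, 3 with the ratios scaled to a common spread, and 0 in Cy5 alone and in Cy3 alone.

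A difference of at least 2-fold with no overlap between the groups was found for 49 genes, 26 with higher and 23 with lower ratios, which are 23 higher and 26 lower if the sign is turned. The groups did not overlap for 49.2% of all genes, where chance gives 33.3%. The count of 2-fold genes was 282 with the scanner software's own log ratio, 280 with the authors' value table, 185 without oxaliplatin replicate 1 and 172 without vehicle replicate 1. Of the 49, 24 had a gene symbol. They included, besides genes already named, the calcium-binding chaperone Calr at 1.08, the astrocyte membrane protein Mlc1 at 1.04, the axonal adhesion protein Nfasc at 1.01, Hoxd10 at -1.09 and Hoxa11 at -1.03, chosen after their values were seen. Each group had a slide of its own, so slide and group cannot be told apart.

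**Figure D2:**
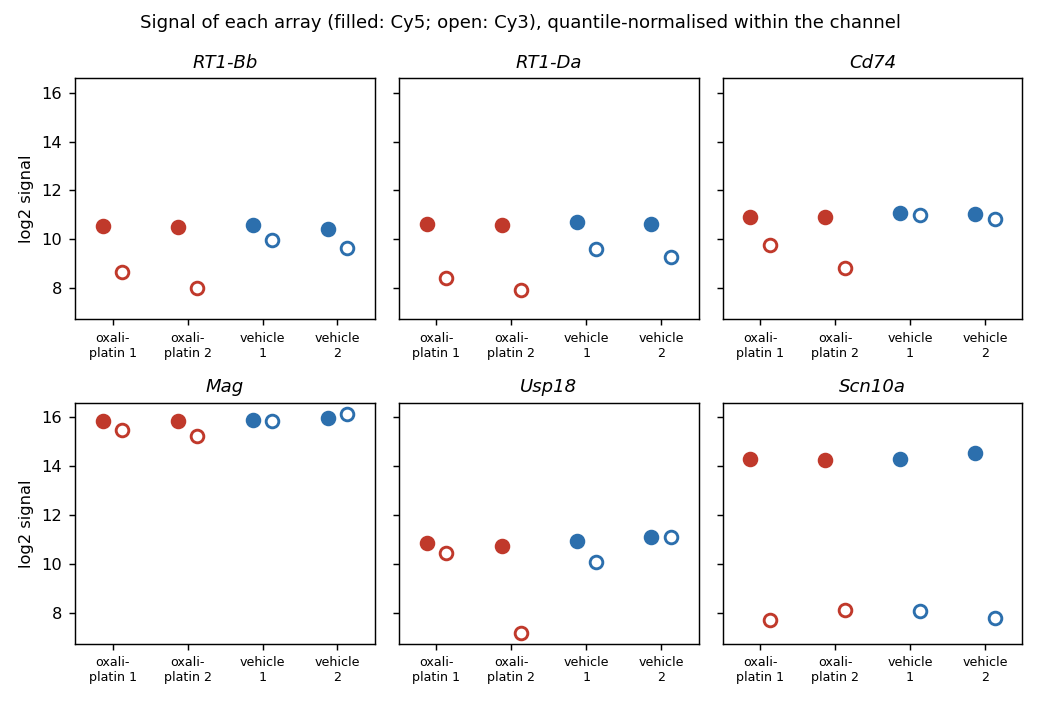
Signal (log2, quantile-normalised within the channel) of 6 genes on each of the 4 arrays, Cy5 as filled and Cy3 as open circles, oxaliplatin arrays in red and vehicle arrays in blue. Cy5 of RT1-Bb, RT1-Da and Cd74 stays near 1 level on all arrays, while their Cy3 signal is lower on the oxaliplatin arrays, by 1.47, 1.27 and 1.62.

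The comparison of the channels within arrays asks which transcripts differed between the RNA in Cy5 and that in Cy3, which the labels call treated and untreated. Genes of the forebrain and of sensory ganglia, tissues outside the cord, were far higher in Cy5 on the vehicle as on the oxaliplatin arrays. Most genes of myelin and of the spinal Hox cluster, which sets position along the cord, were lower in Cy5. The 15 measured forebrain genes had a median log2 ratio of 3.36 on the vehicle arrays and 3.46 on the oxaliplatin arrays. That list was chosen after the data were seen, so its count tests nothing.

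Schwann cell and dorsal root ganglion genes had median ratios of 2.83 and 2.80 on the vehicle and oxaliplatin arrays, with 15 of 16 higher in each group. Their sodium channels Scn11a and Scn10a were at 5.80 and 5.41 on the vehicle arrays, and the peptide gene Calca at 5.58. Immediate early genes, which neurons switch on with activity, had medians of 1.13 and 1.26, with 14 of 22 higher in each group and 2 lower on the oxaliplatin arrays, and Egr4 was at 5.23 on the vehicle arrays. Meningeal and fibroblast genes had medians of 1.03 and 1.24, with 13 and 14 of 17 higher. Oligodendrocyte and myelin genes had medians of -1.34 and -1.12, with 17 of 18 lower in each group, and of -0.98 and -0.66 with median centring in place of loess. Astrocyte markers had medians of -0.89 and -0.38, with 12 and 8 of 16 lower and 3 higher in each group, and of -0.42 and 0.20 with median centring. Gfap was at -1.97 and -1.54. The 13 measured spinal Hox genes had medians of -0.47 and -0.93, with 9 and 10 lower, and of -0.79 and -1.19 with the scanner software's log ratio. The single genes of this comparison were chosen after their values were seen.

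By limma against a ratio of 0, 10383 genes (45.5%) differed on the vehicle arrays, 5333 higher and 5050 lower in Cy5. On the oxaliplatin arrays 7940 genes (34.8%) differed, 4336 higher and 3604 lower. The vehicle count was 6473 without vehicle replicate 1 and 4975 without vehicle replicate 2, and the oxaliplatin count was 12199 with median centring in place of loess. The dyes were not swapped, so a dye effect does not cancel within arrays. Probes were kept by their Cy5 signal alone, so transcripts seen only in Cy3 were left out. The balance of higher and lower genes can depend on that filter.

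**Figure D3:**
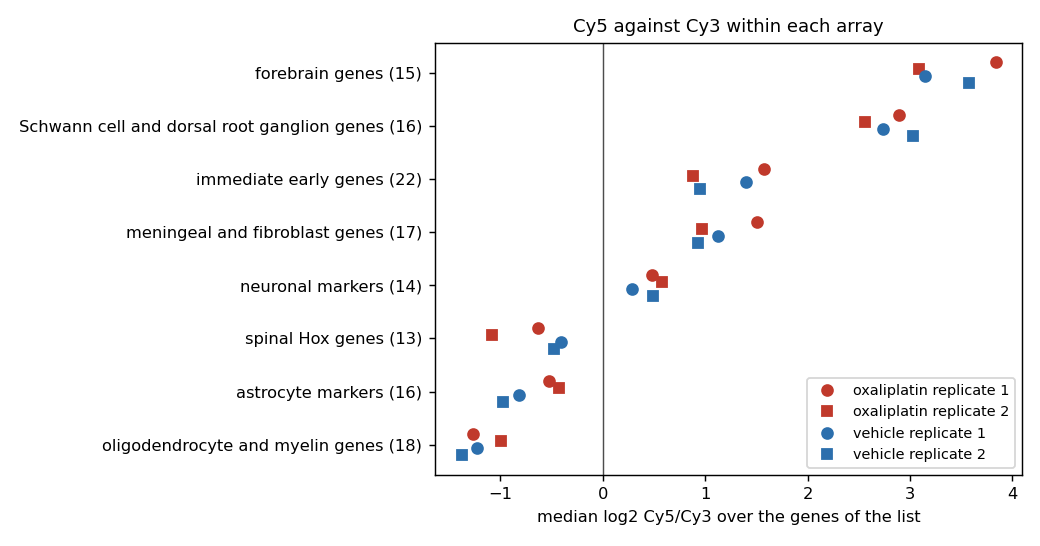
Median log2 Cy5/Cy3 ratio over the measured genes (number in brackets) of 8 lists on each array, oxaliplatin in red and vehicle in blue, replicate 1 as circles and replicate 2 as squares. Forebrain and ganglion lists lie above 2.5 and the Hox, astrocyte and myelin lists below 0 on all 4 arrays, except that with median centring in place of loess the astrocyte median was 0.40 on oxaliplatin replicate 2.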

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

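The settings Cy3 alone, Cy5 alone for the lists, scaled ratios, the added filter on Cy3 and the crossed pairing were chosen only after the results were seen. The calls of the MHC class II, myelin and astrocyte lists kept their direction and their side of the threshold under every alternative run except those named here: estimated correlation, fry, and single channels. Among the 1212 values of 81 named genes under alternatives, 13 turned direction and 42 passed the threshold. The causes of the changes below were not tested, except that fewer arrays were fitted where an array was left out. Signal over background limits which probes were tested: 26002 of 30367 were kept, and Cy3 was well above background for 76.8% of probes on oxaliplatin replicate 2.

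The 3342 genes at an unadjusted p under 0.05 became 929 to 6161 when leaving out an array. Of the 0 genes past the threshold, the count became 1 with trend and robust variance, 3 with the replicate block, 3 with scaled ratios, 537 with the crossed pairing, and 2 to 937 when leaving out an array. The crossed pairing joined oxaliplatin replicate 1 with vehicle replicate 2 and the reverse, a pairing no label gives. The 49 genes with a 2-fold difference became 282 with the scanner software's log ratio, 280 with the authors' value table, and 46 to 185 when leaving out an array.

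The 4 lists called became 8 with median centring, 7 with the replicate block, 0 in Cy5 alone, 0 with an estimated correlation, 0 by fry, and 5 to 10 when leaving out an array. With an estimated correlation and by fry the medians are by construction those of the ratio, 0.42 for astrocyte markers, 0.38 for myelin, 1.19 for MHC class II and -0.10 for ribosomal protein genes, and only the tests differ. In Cy5 alone these medians were 0.040, -0.17, -0.15 and -0.099. In Cy3 alone with its sign turned, the calls of astrocyte markers (0.19) and ribosomal protein genes (-0.079) were lost. Of the 22 lists not described, 10 were called under some alternative: erythrocyte genes with the replicate block (0.29), without oxaliplatin replicate 2 (0.91) and without vehicle replicate 1 (0.61); glucocorticoid response genes with the block (-0.19) and without vehicle replicate 2 (-0.57); cell cycle genes in Cy3 alone with its sign turned (-0.21), without oxaliplatin replicate 2 (-0.18) and without vehicle replicate 2 (-0.21). Complement genes were called without oxaliplatin replicate 2 (-0.20), and motor neuron genes without vehicle replicate 1 (-0.35). Without vehicle replicate 2, endothelial (-0.15), ependymal (-0.30) and immediate early genes (-0.28) were called. With median centring neutrophil and monocyte genes (-0.30) and oxidative stress genes (0.16) were called. The ribosomal median was -0.0040 with median centring, where the test turned, and -0.16 to -0.064 when leaving out an array.

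Lists not called that turned direction in Cy5 alone were microglia markers (-0.12), reactive astrocyte genes (0.013), cytokines (0.055), neuronal markers (-0.12), excitatory (-0.050) and inhibitory (0.022) neuron genes, p53 targets (0.043), nerve injury genes (-0.0088), interferon genes (-0.033) and lymphocyte genes (-0.039). The test of p53 targets also turned with median centring (0.17) and with the mean over probes (0.061), and that of lymphocyte genes with median centring (-0.33). Leaving out an array turned the direction within these ranges: microglia markers -0.17 to 0.35, neuronal markers -0.069 to 0.18, p53 targets -0.065 to 0.044, nerve injury genes -0.029 to 0.095, interferon genes -0.29 to 0.83, Schwann cell and ganglion genes -0.31 to 0.075, and lymphocyte genes 0.0024 to 0.070. For p53 targets and lymphocyte genes the test turned while the median need not, and for neuronal markers the median turned while the test did not. The medians of microglia markers with no background correction (-0.0012) and of reactive astrocyte genes with scaled ratios (0.013) also turned. So did those of p53 targets (-0.050) and lymphocyte genes (0.016) in Cy3 alone with its sign turned. Other moves of medians by over 1.5 times included these. In Cy3 alone with its sign turned: microglia markers 0.088, reactive astrocyte genes -0.065, cytokines -0.035 and neuronal markers 0.14. Also there: excitatory 0.041 and inhibitory -0.15 neuron genes and Schwann cell genes -0.014. Schwann cell genes were at -0.084 in Cy5 alone. With median centring: microglia markers 0.079, reactive astrocyte genes -0.094, neuronal markers 0.12, excitatory 0.15 and inhibitory -0.010 neuron genes, nerve injury genes 0.064 and Schwann cell genes -0.066. With the scanner software's log ratio: microglia markers 0.021, neuronal markers 0.0084, excitatory 0.0086 and inhibitory -0.15 neuron genes, p53 targets 0.023, nerve injury genes 0.062, Schwann cell genes -0.077 and lymphocyte genes -0.013. With the mean over probes: reactive astrocyte genes -0.071, neuronal markers 0.062, inhibitory neuron genes -0.076 and nerve injury genes 0.12. With scaled ratios: microglia markers 0.030, excitatory 0.031 and inhibitory -0.070 neuron genes, nerve injury genes 0.064, Schwann cell genes -0.0076 and lymphocyte genes 0.0040. Cytokines were at -0.11 with the filter on all 4 arrays. Lymphocyte genes were at 0.0085 with that filter, -0.014 with no filter and 0.00034 with no background correction.

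Of 81 named genes, 48 moved by over 1.5 times or turned under some alternative, 34 of them when leaving out an array. Single genes turned as follows. With median centring Aif1 was 0.069 and Oasl -0.28. With the mean over probes Aif1 was 0.050, Cxcl12 -0.031 and Csf1r 0.0065, and with scaled ratios Aif1 was 0.030. Leaving out an array gave Aif1 -0.49 to 0.44, Tnf -0.29 to 0.73, Il1b -0.67 to 0.15, Serpina3n -1.91 to 0.22, Mrgprx3 -0.41 to 0.0030 and Prf1 -0.33 to 0.057. Within arrays, the vehicle count of 10383 genes was 4975 to 12114 when leaving out an array, and the oxaliplatin count of 7940 was 12199 with median centring. The astrocyte median on the oxaliplatin arrays, -0.38, turned to 0.20 with median centring, and that on the vehicle arrays, -0.89, became -0.42. The myelin medians of -1.34 (vehicle) and -1.12 (oxaliplatin) became -0.98 and -0.66. The Hox medians of -0.47 and -0.93 became -0.79 and -1.19 with the scanner software's log ratio.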

Other observations

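Some genes varied more between arrays of a group than between the groups, and did so in Cy3. These genes were chosen only after their values were seen. Usp18, which restrains interferon signalling, had log2 Cy5/Cy3 ratios of -0.68 and 2.47 on oxaliplatin replicates 1 and 2 and of -0.16 and -1.10 on vehicle replicates 1 and 2. Its Cy3 signal was 10.44, 7.18, 10.05 and 11.11 (log2) on those arrays, and its Cy5 signal 10.83, 10.73, 10.94 and 11.09. Isg15, Irf7 and Oas1a, other genes of the interferon response, ranged over 3.64, 3.31 and 3.59 in Cy3 and over 0.49, 0.28 and 0.56 in Cy5. The haemoglobin gene Hbb had ratios of 2.78 and 0.35 on the oxaliplatin and 1.25 and 0.08 on the vehicle arrays, with a range of 2.24 in Cy3 and 0.26 in Cy5. Sgk1, a kinase induced by glucocorticoids, had ratios of -0.17, -0.66, 1.91 and -0.91.

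In the patterns weighed next, the Hox test, the tests against genes of the same mean ratio and the counts of splits for lists and 2-fold genes were written before their values were seen; all other tests were chosen only after the results were seen. The test against genes of the same mean ratio was written for both lists together and was divided by list afterwards, with its bound unchanged.

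The Cy5 channel carried ganglion transcripts on all 4 arrays. The ganglion genes' median ratio of 2.79 lay at percentile 100 of 10000 random lists of like signal, whose 95% range ended at 0.23. That argues only against a dye effect that depends on signal, which loess also fits. A dye effect particular to these genes was not tested, since the dyes were not swapped. If Cy5 held RNA from outside the cord, the spinal Hox genes should be low in it, and their median of -0.67 lay at percentile 0 of random lists (95% range from -0.18), with 13 of 13 below 0. The interferon genes, taken because their ratios varied between arrays, had a range over the arrays 3.70 times as large in Cy3 as in Cy5. Over all genes the median SD over the arrays was 0.14 in Cy5 and 0.20 in Cy3, a smaller gap. A candidate explanation is that Cy5 held a reference RNA of several tissues. If Cy3 then held the treated rats' RNA, against the labels, every oxaliplatin minus vehicle difference of the ratio would point the other way in the rats. If Cy3 held untreated RNA, as the labels state, neither channel would then hold treated RNA and no direction could be read. Single-channel and within-array values would keep their sign. No record used here states that explanation, and no biological explanation was tested.

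The myelin and astrocyte genes had higher ratios on the oxaliplatin arrays as groups, although the myelin list's median ratio of -1.27 on oxaliplatin replicate 1 lay below the -1.23 on vehicle replicate 1. Both calls were lost with an estimated correlation (adjusted p = 0.923 with an estimated correlation). Ratios on oxaliplatin replicate 2 had a slope of 0.75 on those of the other arrays, but of 0.94 with median centring and 0.82 with the scanner software's log ratio. Compressed ratios there are argued against as the whole cause, because without that array the lists kept 0.62 (myelin) and 0.70 (astrocyte) of their medians. Among random lists of the same mean ratio, the myelin median lay at percentile 96.53, within the 95% range, and the astrocyte median at percentile 99.95, beyond it. The myelin difference may therefore be part of a trend of all genes with low ratios. For the astrocyte list the percentile cannot exclude that trend. The random lists were drawn gene by gene, while the astrocyte markers moved together (estimated correlation 0.13). Slide and group cannot be told apart for either list, since each group had its own slide, and an effect of oxaliplatin on these cells stays open and untested.

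Of the 7 MHC class II genes, 4 had ratios higher by over 1, with lower Cy3 signals, and 3 differed by 0.17, -0.010 and -0.036. The list's call was lost with an estimated correlation (adjusted p = 0.923 with an estimated correlation). A different number of microglia is argued against as the whole cause of the group difference. The microglia markers had a median of 0.0044 (SD 0.21 over members, not over arrays) against 1.19 for MHC class II. When leaving out an array these medians were -0.17 to 0.35 and 0.98 to 1.39. Both lists were higher on oxaliplatin replicate 2 than on replicate 1 (microglia -0.013 against -0.51). A part of microglia in that gap stays open. A change in class II expression within cells may also underlie the higher ratios. Whether it would be a treatment effect or a difference between the rats or slides stays open. Sequence variants of the MHC under the probes stay open too, since of the 2 members outside the MHC, Cd74 and Ciita, 1 differed by over 3 of its standard errors, and RT1-DMa and RT1-DMb within the MHC hardly differed. The test would be RT1-Da and Cd74 in more rats of each group, with the dyes swapped.

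The 4 arrays can be split into 2 pairs in 3 ways, too few for a share under 0.05. The real split called 4 lists and the highest other split 8, so that all 3 splits called as many. The real split gave 49 genes with a 2-fold difference and the highest other 57, so that 2 of 3 splits gave as many. At an unadjusted p under 0.05 the real split gave 3342 genes and the highest other 541, so that only the real split, 1 of 3, gave as many. The real split is also the split by slide. The other splits gave 262 and 541, below the 1141 of chance alone, since a difference between groups or slides counts as residual spread in them. Their counts are therefore no measure of chance for the real split. Both other splits called 8 lists and were led by the erythrocyte genes (adjusted p = 5.05e-12) and by the interferon genes (adjusted p = 3.71e-24), which points to differences between arrays within groups. With an estimated correlation all 3 splits called 0 lists, also the split led by the interferon genes. That setting, with a residual df of 2, therefore cannot tell the splits apart.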
